A study of Rattus norvegicus with 6 samples.

How the data were processed

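Bladder tissue of 3 saline and 3 ketamine-treated rats was profiled by sequencing of total RNA, per the labels. Groups follow the treatment given in the labels, replicates are numbered in accession order within a group and do not pair rats. The sample titles hold codes with the letters h or L for ketamine and o for saline, which the labels do not explain; whether they stand for batches, doses or rats handled apart is not given in the sources used here, and no covariate was made of them. The series' design text gives 3 rats per group. Tissue was rinsed, cut and cleared of clots, connective tissue and fat, per the labels' protocols.

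The deposited tables give raw read counts per gene for mRNA, per transcript for lncRNA, per mature miRNA, and back-splice junction counts per circRNA, per the file headers. Beside the counts, the authors gave FPKM for mRNA and lncRNA, a column named Tpm for miRNA that equals RPM computed from the counts, and for circRNA a signal of junction reads scaled to a library total, per the file headers. The lncRNA table also gives a length in bases, per the file headers. The aligner, the counting program, the circRNA caller and the annotation version are not given in the sources used here. Per the submitters' processing notes, the build was mm9, which is a mouse build, although the organism is rat and gene identifiers are rat identifiers. Coordinates are printed as the tables give them, and the rat build behind them is not given in the sources used here. The circRNA table holds no junction count of 1, with a smallest value of 2. The junction signal implies a total per library that is a multiple of 150, so it was read as bases, equal to 67173016 to 81756911 reads of 150 bases. Of the lncRNA rows, 478 repeat the position and all 6 counts of an mRNA row.

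All tests used the counts as deposited. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr with a minimum count of 10, no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05, run for each RNA class. It kept 14014 of 30957 mRNA rows, 11363 of 21814 lncRNA rows, 355 of 794 miRNAs and 264 of 9473 circRNAs. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of its F statistic. CPM values are counts over 1e6 counts of the TMM-scaled library, and list medians per library use log2 CPM with a prior count of 2. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, and miRNA lists where at least 2 arms were. Of 38 gene lists, 35 had enough tested members; accessory sex gland genes had 0, and B cell and neutrophil genes had 4 each. Symbols were matched to the table's gene names or, through the RefSeq gene table, to their older names. A circRNA was matched to its host gene by the identifier in the table.

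Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, limma voom, voom with library weights, no filter, a stricter filter (a minimum count of 50, or for circRNAs a count above 0 in all 6 libraries), each library left out in turn, and for lists an estimated correlation, fry and ranks. For circRNAs this filter was not stricter in effect. It kept 353 circRNAs with a tested host gene, against 225 with the main filter. Chosen after seeing the data were voom with quantile normalization for the numbers of RNAs called, coding genes only, lncRNA rows summed to loci, the mRNA table's scaling for lncRNAs, circRNA counts scaled to total reads, the list of Dlk1-Dio3 miRNAs, the same list without its 5 named members, and the estimated correlation for gene lists without each library and in each split of the libraries. Settings meant for normalized values (pseudocounts, median scaling, moderation without a trend) do not apply to counts and were not run. Quantile normalization was run within voom, on log2 CPM, for each RNA class, for lists and for named RNAs. Groups of 3 give at best a two-sided p of 0.1 in an exact permutation test, so single values carry the adjusted p of the model.

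Genes were named by a rule fixed before the data were examined. For mRNA it took up to 10 genes per direction past the threshold with groups that do not overlap, skipping rows without a gene name of their own, filled to 5 by smallest p where fewer passed. To these it added a panel of 12 genes of fibrosis, urothelium, inflammation and the NMDA receptor, and up to 4 members per described list with the smallest adjusted p. For the other classes it took 5 per direction, again filled by smallest p, and for miRNAs also 8 named in advance, each by its most abundant arm.

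The scripts were tested on simulated data drawn from the real means, dispersions and library sizes. The number of changed genes was 200 for mRNA and lncRNA, 44 for miRNA and 33 for circRNA. edgeR called 7.58% of 66 genes changed 2-fold, 80.3% of 66 changed 4-fold and all of 65 changed 16-fold for mRNA, over 13808 tested genes, with 6 false calls among 129. For lncRNA, over 10693 rows, it called 1.56% of 64, 9.38% of 64 and 84.6% of 65, with 5 false calls among 67. For miRNA, over 337, it called 46.7% of 15 changed 2-fold and all 14 changed 4-fold, with 5 false calls among 40. For circRNA, over 218, it called 11.1% of 9 changed 2-fold and 77.8% of 9 changed 4-fold, with 1 false call among 19. A simulated list of 20 genes changed 2-fold was called, and 0 of 50 unchanged lists were. The simulated genes were drawn independently of each other. This does not test the preset correlation on real lists, whose members vary together between rats.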

Results

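Bladder tissue came from 6 Sprague-Dawley rats, an outbred laboratory strain. Of these, 3 received ketamine hydrochloride, an NMDA receptor blocker used as an anaesthetic, at 25 mg per kg per day, and 3 received saline. The series set these groups side by side as a rat model of bladder fibrosis caused by ketamine. The tables hold 1 column per rat for each RNA class. Counts were analysed for mRNA genes, long noncoding RNAs (lncRNAs), mature microRNAs (miRNAs) and circular RNAs (circRNAs), the last counted by reads that cross a back-splice junction. Total counts per library ran from 9400340 to 17851818 for mRNA, from 1795793 to 2281902 for lncRNA, from 7483924 to 13419624 for miRNA and from 10266 to 129648 for circRNA junction reads. Ketamine replicate 3 held both the highest mRNA total and the 129648 junction reads, and the other 5 libraries reached at most 20348. Throughout, a positive log2 fold change means higher with ketamine, and group values are normalised CPM, mean ± SD over 3 rats.

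The mRNA comparison asked which genes differ in the bladder of ketamine-treated rats. Paxillin (Pxn), a scaffold protein of focal adhesions, had 26.3 ± 3.13 CPM with saline and 82.8 ± 6.93 with ketamine (SD, n = 3 each), a log2 fold change of 1.65 (SE 0.19). The mast cell receptor gene Ms4a2, the beta chain of the high-affinity IgE receptor, had 3.68 ± 0.849 CPM with saline and 0.783 ± 0.327 with ketamine. Scn9a, a voltage-gated sodium channel of sensory neurons, had 3.40 ± 0.449 and 1.01 ± 0.286 CPM. None of these passed the test over all genes: 0 of 14014 genes reached an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 430 had an unadjusted p under 0.05, limma voom called 0, and DESeq2 called 4. Chance gives 701 genes at an unadjusted p under 0.05, more than the 430 seen. The other splits of the libraries into 3 and 3 gave 167 to 1947. The 4 DESeq2 calls were Pxn (adjusted p = 1.4e-11) and Rab3b (0.0051), higher, and an H3f3b row (1.9e-12) and Muc16 (0.039), lower. Muc16 is named because DESeq2 called it, after its values were seen.

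Among the higher values with the smallest p-values, Rab3b, a small GTPase of regulated secretion, had a log2 fold change of 1.57 (SE 0.29), from 8.59 ± 0.389 to 25.5 ± 8.05 CPM. The heparan sulfate enzyme gene Ndst4 had 1.34 (SE 0.33), Tmem141 had 1.26 (SE 0.33) and the flavin monooxygenase gene Fmo6 had 2.69 (SE 0.72), the last from 0.316 ± 0.0773 CPM with saline; without ketamine replicate 3 the Fmo6 value was 1.74. Among the lower values, a row named H3f3b, a histone H3.3 gene, on chromosome 13 (99091763 to 99101208) had a log2 fold change of -3.50 (SE 0.41), with 300 to 802 reads per saline library and 35 to 75 per ketamine library. A second row with the same symbol, on chromosome 10, had a log2 fold change of 0.41 and 2941 to 7372 reads. Whether reads were split between these rows was not tested, so the chromosome 13 value is uncertain. Kcnv2, a modifier subunit of potassium channels, had -1.37 (SE 0.31), Ms4a2 had -2.24 (SE 0.46), Scn9a had -1.74 (SE 0.40) and Ano5, an anoctamin membrane protein gene, had -3.28 (SE 0.78). For these 10 genes the groups did not overlap in any library. The edgeR quasi-likelihood adjusted p was 0.252 for Pxn and H3f3b and 0.925 for the other 8. Groups did not overlap for 7.52% of all tested genes, where chance gives 10%.

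**Figure D1:**
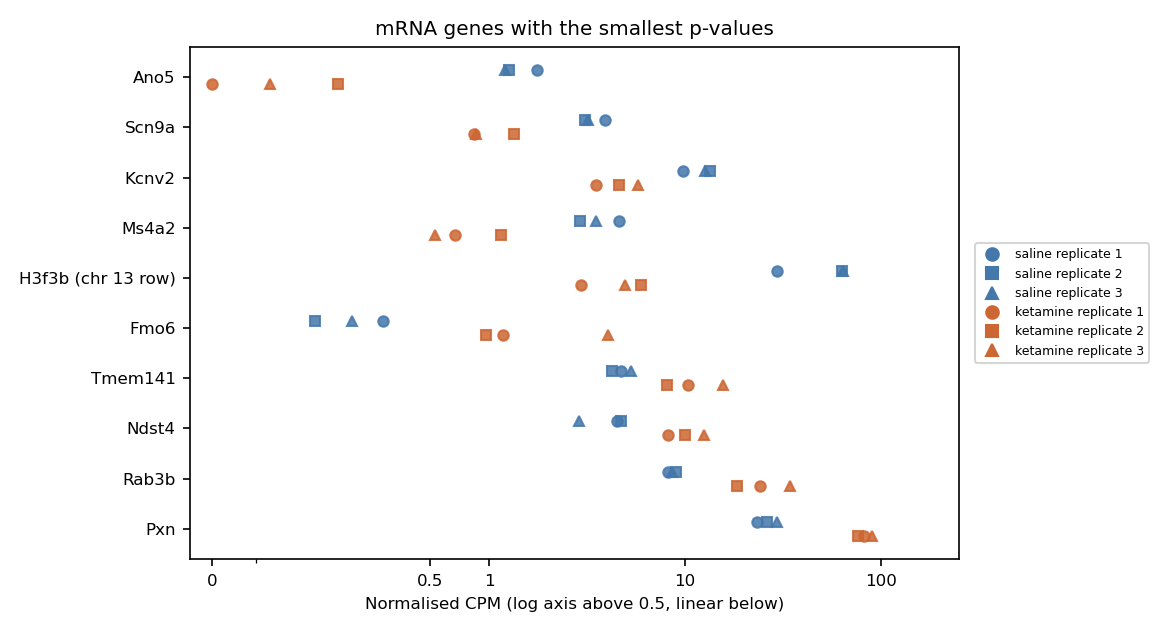
Normalised CPM (log axis above 0.5, linear below) in each of the 6 libraries for the 10 named mRNA genes with the smallest p-values in either direction; colours stand for groups and symbols for replicates. Pxn sits at 26.3 ± 3.13 CPM with saline and 82.8 ± 6.93 with ketamine (SD over 3 rats), and the groups do not overlap for any of the 10 genes.

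Genes of fibrosis and of the bladder wall differed by less than the test could separate from the spread between rats. The collagen genes Col1a1 and Col3a1, the main fibrillar collagens of scar tissue, had log2 fold changes of -0.62 (SE 0.42) and -0.46 (SE 0.34). Col1a1 had 1950 ± 762 CPM with saline and 1271 ± 494 with ketamine. Fibronectin (Fn1) had 0.17 (SE 0.33), smooth muscle actin (Acta2) 0.26 (SE 0.52), Tgfb1, the cytokine TGF-beta, 0.47 (SE 0.30) and Timp1, an inhibitor of matrix proteases, 0.21 (SE 0.38). Connective tissue growth factor (Ccn2, listed as Ctgf) had -0.90 (SE 0.49), and -1.68 without ketamine replicate 1 or -0.53 without ketamine replicate 3. The urothelial plaque genes Upk2 and Upk3a had 0.01 (SE 0.56) and 0.70 (SE 0.49), and the cyclooxygenase gene Ptgs2 had 0.55 (SE 0.86). Without ketamine replicate 3, Upk3a had 0.11, Tgfb1 0.16 and Col1a1 -0.35, and without saline replicate 3 Col1a1 had -0.28. The direction was not stable for Fn1, Acta2, Timp1, Upk2 and Ptgs2, each of which turned negative with quantile normalization or without 1 library. The smallest edgeR adjusted p among these 10 genes was 0.925. Il6 and the NMDA receptor subunit gene Grin1 had too few reads to test, at 0 to 2 and 0 to 15 per library.

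Of 35 gene lists fixed before the data were examined, 7 were past the threshold against the other genes (camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). Mast cell and eosinophil genes, adipocyte genes, collagens, Schwann cell and neuron genes, and immediate early and heat shock genes fell as lists. Ribosomal proteins and nuclear-encoded oxidative phosphorylation genes rose. With a correlation estimated for each list, none of the 7 held (adjusted p = 0.833 for each with an estimated correlation), and fry, which does not compare with other genes, also called 0 (adjusted p = 0.977 for each). At an unadjusted p under 0.05, camera with the estimated correlation gave 0 lists and fry 0. The real grouping gave 7 such lists, and the 9 other ways to split the 6 libraries gave 5 to 20.

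Of the 9 tested mast cell and eosinophil genes, 0 passed over all genes and 1, Ms4a2, passed when adjusted over the list alone; 6 had negative and 3 positive values. The median log2 fold change was -0.83 (camera adjusted p = 2.9e-05, and 0.833 with an estimated correlation). Mcpt2, a mast cell protease, had 473, 507 and 7 reads with saline and 0, 4 and 50 with ketamine, Fcer1a, the alpha chain of the IgE receptor, had 1.26 ± 0.348 and 0.314 ± 0.272 CPM, and Cpa3, a mast cell carboxypeptidase, had 9.28 ± 1.97 and 4.29 ± 3.13. The list median per library, as log2 CPM less the mean of the 6, was 0.43 to 0.64 with saline and -1.74, 0.32 and 0.01 in ketamine replicates 1, 2 and 3. With the preset correlation the list call was kept without each library in turn, with medians from -1.52 to -0.57, and with an estimated one it was past the threshold in none of these 6 fits (adjusted p = 0.319 to 0.982). The log2 fold change of Cpa3 was -1.11, and -0.61 without ketamine replicate 1, and that of Mcpt2 was -4.47, and -7.23 without ketamine replicate 3.

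Adipocyte genes had a median log2 fold change of -0.66 over 16 tested members, 12 negative and 4 positive, with 0 passing over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.00014, and 0.833 with an estimated correlation). Scd1, a fatty acid desaturase, had 163 ± 175 CPM with saline and 19.2 ± 11.3 with ketamine, and lipoprotein lipase (Lpl) had 145 ± 82.7 and 73.5 ± 13.3. The list median per library was 0.93 in saline replicate 1, -0.33 in saline replicate 2 and 0.49 in saline replicate 3, against -0.62 to -0.15 with ketamine. Per the labels, visible fat and connective tissue were removed before extraction. Of 13 Schwann cell and neuron genes, 9 were negative, 4 positive, and 0 passed over all genes or when adjusted over the list alone (median -0.40, camera adjusted p = 0.017, and 0.833 with an estimated correlation). The glial marker S100b had 33.2 ± 20.5 CPM with saline and 16.4 ± 3.82 with ketamine. The Schwann cell and neuron median was -0.80 without ketamine replicate 2, -0.74 without saline replicate 2 and -0.22 without ketamine replicate 3. Without saline replicate 1 the adipocyte median was -0.38 (adjusted p = 0.0496 with the preset correlation), and the log2 fold change of Scd1 went from -3.08 to -1.74, that of Lpl from -0.98 to -0.42 and that of S100b from -1.01 to -0.45.

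The fibrillar and network collagens had a median log2 fold change of -0.29 over 17 tested genes, 12 negative and 5 positive, 0 passing over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.017, and 0.833 with an estimated correlation). The median ranged from -0.69 (without ketamine replicate 1) and -0.62 (without saline replicate 2) to -0.16 (without ketamine replicate 3) and -0.095 (without saline replicate 3). Col5a3, a minor fibrillar collagen, had -1.22 (SE 0.51). Of 24 immediate early and heat shock genes, 19 were negative and 5 positive, and 0 passed over all genes or when adjusted over the list alone (median -0.31, camera adjusted p = 0.013, and 0.833 with an estimated correlation). The chaperone genes Hspa1b and Hsph1 had -1.57 (SE 0.38) and -0.91 (SE 0.35), and Hsph1 had -0.56 without saline replicate 2. Egr3 had -2.57, and 0.45 without saline replicate 3. Ier3 went the other way with 0.98, and 0.44 without ketamine replicate 3. The median of this list was 1.02 in saline replicate 3 and -0.43 and -0.33 in saline replicates 1 and 2, against 0.57, -0.49 and -0.73 in ketamine replicates 1, 2 and 3. Its median was -1.09 without ketamine replicate 1, -0.64 and -0.58 without saline replicates 1 and 2, and 0.47 without saline replicate 3 (adjusted p = 0.497). The collagen call was lost without saline replicate 1 (adjusted p = 0.238, median -0.25), saline replicate 3 (0.536), ketamine replicate 2 (0.405, median -0.22) or ketamine replicate 3 (0.260). The heat shock call was also lost without ketamine replicate 2 (0.399, median -0.14) or 3 (0.210, median -0.16). The Schwann cell call was lost without saline replicate 1 (0.208, median -0.45) or 3 (0.051, median -0.29).

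The higher lists followed ketamine replicate 3. Of 27 ribosomal protein genes, 26 were positive and 1 negative, and 0 passed over all genes or when adjusted over the list alone (median 1.29, camera adjusted p = 1.3e-10, and 0.833 with an estimated correlation). Rps15 had 297 ± 75.0 CPM with saline and 1203 ± 1380 with ketamine, and Rpl27 had 89.5 ± 4.14 and 287 ± 300.3. Of 33 oxidative phosphorylation genes, 32 were positive and 1 negative, again with 0 passing over all genes or when adjusted over the list alone (median 0.69, camera adjusted p = 1.3e-10, and 0.833 with an estimated correlation). Cox7a2, a subunit of cytochrome c oxidase, had 1.91 (SE 0.73) and Ndufa5, a complex I subunit, had 1.01 (SE 0.41). The list medians in ketamine replicate 3 were 1.87 and 1.18, against at most -0.08 and 0.13 in the other 5 libraries. Without ketamine replicate 3 the medians dropped to 0.14 and 0.17, past the threshold with the preset correlation (adjusted p = 0.015 and 0.0032) and not with an estimated one (adjusted p = 0.781 and 0.793). Rps15, Rpl27, Cox7a2 and Ndufa5 then had log2 fold changes of 0.46, 0.35, 0.55 and 0.39.

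Cell types of the bladder wall and blood varied between rats within each group. Macrophage genes had a median log2 fold change of 0.72, 20 positive and 1 negative of 21 (camera adjusted p = 0.065, and 0.911 with an estimated correlation). Their median was 1.71 in ketamine replicate 3 and -0.93 and -0.43 in ketamine replicates 1 and 2. Without ketamine replicate 3 it was -0.50, past the threshold in the other direction with the preset correlation (adjusted p = 6.1e-11) and not with an estimated one (adjusted p = 0.650, a test chosen after seeing the data). Smooth muscle contractile genes had a median of 0.02 over 24 genes, with 0.77 in ketamine replicate 1 and 0.45 in saline replicate 1, against -0.40 and -0.52 in ketamine replicates 2 and 3 and -0.49 in saline replicate 2. The camera test pointed down (adjusted p = 0.711), while the median and the mean of 0.05 were positive. Urothelial genes had medians of -0.76, 0.51 and 0.08 in ketamine replicates 1, 2 and 3 and -0.77, 0.66 and 0.35 in saline replicates 1, 2 and 3. Their list median was -0.19 over 28 genes, 6 positive and 22 negative (camera adjusted p = 0.265). It turned to 0.13 without saline replicate 2 and 0.10 without ketamine replicate 1. Without saline replicate 1 it was -0.50, and without ketamine replicate 2 it was -0.49. The smooth muscle median ranged from -0.51 (without ketamine replicate 1) to 0.27 (without ketamine replicate 3). The replicate numbers do not pair rats. The basal urothelial gene Tp63 had 59.4 ± 5.15 CPM with saline and 126 ± 58.1 with ketamine, and the smooth muscle kinase Mylk had 4218 ± 1508 and 1811 ± 777 (both edgeR adjusted p = 0.925); the log2 fold change of Tp63 was 1.09, and 0.63 without ketamine replicate 2. All 10 MHC class II genes were positive, with a median of 0.54 (camera adjusted p = 0.057), and without ketamine replicate 3 the median was 0.01 (adjusted p = 0.892).

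**Figure D2:**
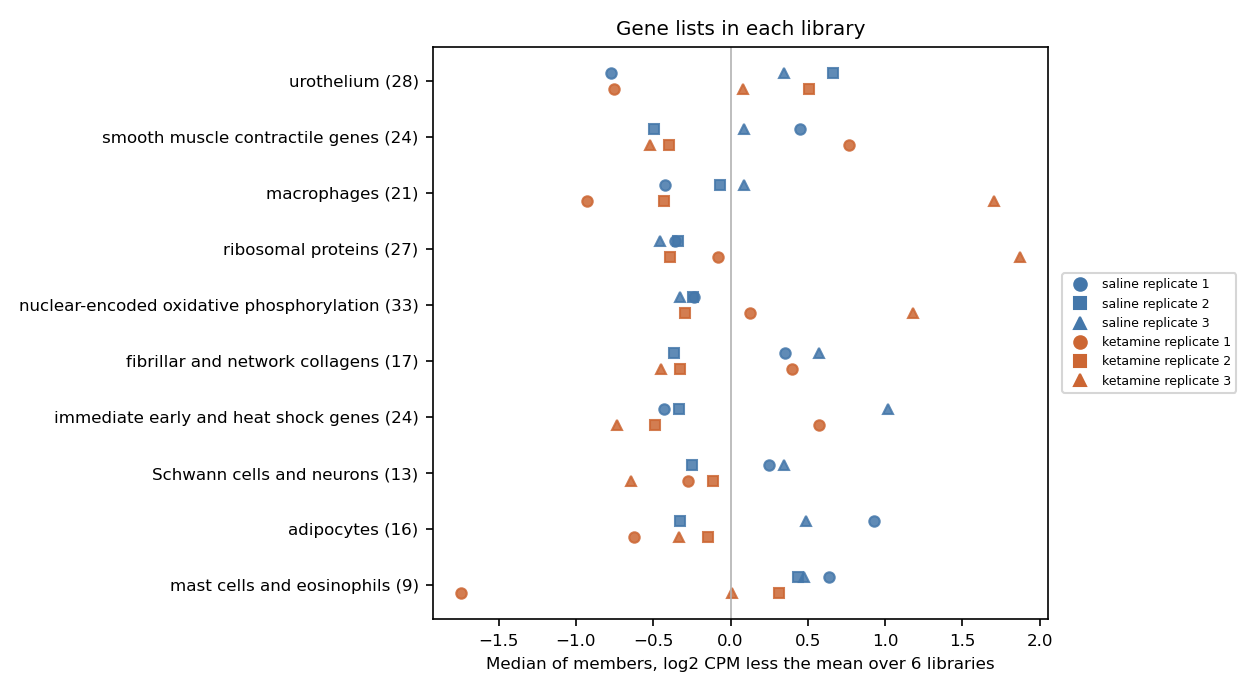
Median over the members of each gene list (number tested in brackets) of log2 CPM less the gene's mean over the 6 libraries, for the 7 lists past the camera threshold and for macrophages, smooth muscle and urothelium; colours stand for groups and symbols for replicates. Ribosomal proteins, oxidative phosphorylation and macrophage genes reach 1.87, 1.18 and 1.71 in ketamine replicate 3 alone.

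The lncRNA comparison asked the same of 11363 tested rows. Here 1 lncRNA rose and 3 fell (edgeR quasi-likelihood test, Benjamini-Hochberg), with 465 at an unadjusted p under 0.05, where chance gives 568. The other splits of the libraries gave 217 to 1160 at that p. The assembled transcript MSTRG.21633.2 on chromosome 2 (27412832 to 27419076), overlapping Col4a3bp, a ceramide transporter gene, rose from 0, 0 and 1 reads to 265, 295 and 192 (adjusted p = 0.0094). MSTRG.18336.2 on chromosome 17 (63469850 to 63478688) fell from 1034 to 1597 reads per saline library to 0 to 2 per ketamine library (adjusted p = 0.010). NONRATT026771.2 on chromosome 7 (60390515 to 60391533), an unspliced transcript at the Cpsf6 locus, which encodes a pre-mRNA cleavage factor, fell from 180 to 259 reads to 1 in each ketamine library (adjusted p = 0.0037). NONRATT003219.2 on chromosome 1 (199057773 to 199059254), an unspliced transcript at the zinc finger gene Zfp629, fell from 131 to 233 reads to 4 or 5 (adjusted p = 0.010). Its log2 fold change was -5.04 (SE 0.41).

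From summed reads, MSTRG.21633.2 was 909-fold higher with ketamine (95% counting interval 163 to 35948, exact binomial). That fold rests on 1 saline read, in saline replicate 3. Without that library its edgeR log2 fold change went from 9.32 to 11.06. NONRATT026771.2 was 183-fold lower (62.4 to 890.2) and MSTRG.18336.2 was 1530-fold lower (423 to 12640). These intervals cover counting error only. The 2 ketamine reads of MSTRG.18336.2 were in ketamine replicate 2, and without that library its edgeR log2 fold change went from -10.39 to -13.18. The overlapping Col4a3bp and Cpsf6 mRNA rows had log2 ratios of -0.14 and -0.38 between groups, and Zfp629 had 0.05. Some rows of the same loci went the other way, and others did not. MSTRG.21633.1 had 479 to 688 reads per saline library and 0, 230 and 0 in the ketamine libraries, and MSTRG.18336.3 had 0, 0 and 105 with saline and 380 to 931 with ketamine. In the locus of MSTRG.18336.2, MSTRG.18335.9 and MSTRG.18339.1 had log2 ratios of -0.44 and -0.66, the direction of MSTRG.18336.2 itself. These rows do not overlap MSTRG.18336.2 and share its locus only through the longer row NONRATT012572.2 (63426749 to 63777621), so they say nothing on exchange of reads with it. MSTRG.18336.3 does overlap it. NONRATT003219.2 overlapped no other lncRNA row. Reads shared by overlapping transcripts of one locus, or by a transcript and the gene on the other strand, cannot be told apart where the counting is not given in the sources used here. The next rows did not pass: MSTRG.9906.3 was at least 257-fold lower with ketamine and MSTRG.41588.17 and MSTRG.37828.2 at least 67.7-fold and 37.9-fold higher, against a floor of 3 reads over the group. Their edgeR adjusted p-values were 0.053, 0.059 and 0.099. NONRATT000286.2 and NONRATT019429.2 had log2 fold changes of 4.76 (SE 0.62) and 5.28 (SE 0.73), and NONRATT000863.2 had -4.78 (SE 0.55). DESeq2 called 32 lncRNAs, among them the 4 called by edgeR and all of the next rows named here, and limma voom called 0. Summing overlapping rows to loci, an alternative chosen after seeing the data, left 1 call, the locus of NONRATT003219.2, and without saline replicate 2 the only call was NONRATT026771.2.

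**Figure D3:**
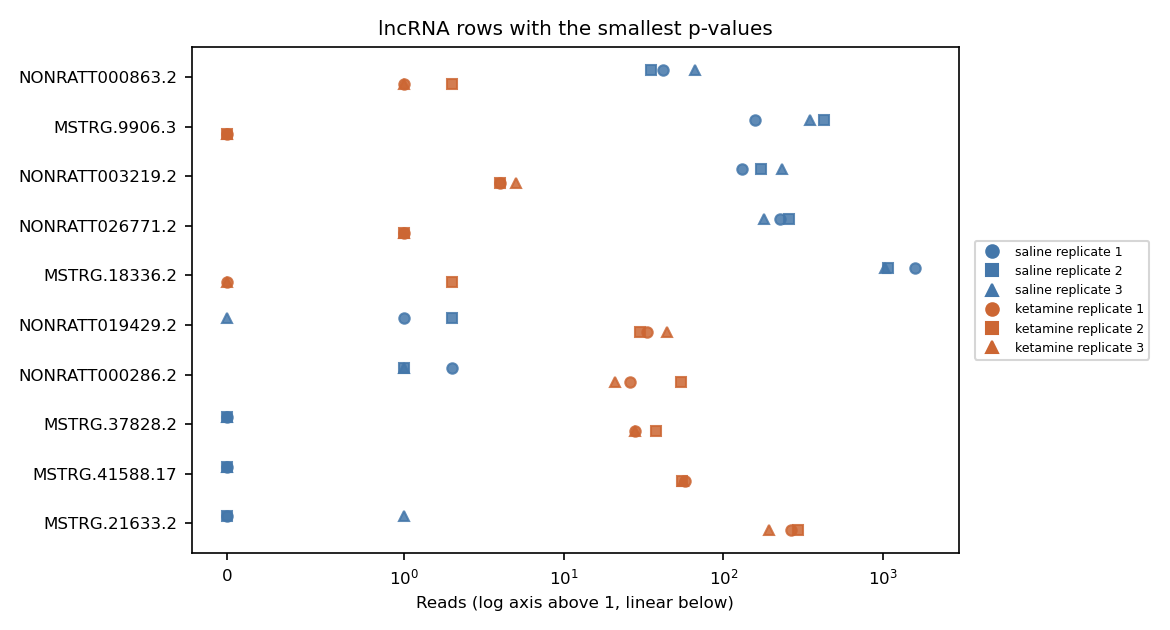
Reads per library (log axis above 1, linear below) for the 10 named lncRNA rows, with colours for groups and symbols for replicates. For MSTRG.18336.2 the saline libraries hold 1034 to 1597 reads and the ketamine libraries 0 to 2.

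Among 355 tested miRNAs, the 5 with the smallest p-values on the higher side were miR-411-5p, miR-379-5p, miR-494-3p, miR-154-5p and miR-337-5p, all encoded in the imprinted Dlk1-Dio3 locus. miR-411-5p had 50.1 ± 7.11 CPM with saline and 95.1 ± 12.5 with ketamine (SD, n = 3 each), and miR-379-5p had 62.1 ± 9.13 and 113 ± 36.2. The log2 fold changes of the 5 lay between 0.75 and 1.58, and the groups did not overlap for any of them. On the lower side, miR-101a-3p had 1152 ± 796 CPM with saline and 481 ± 35.2 with ketamine, and miR-126a-5p, from an endothelial miRNA gene, had 407 ± 41.5 and 238 ± 15.3. miR-7b had a log2 fold change of -1.96 (SE 0.64), miR-30a-3p -1.11 (SE 0.36) and miR-125b-2-3p -0.95 (SE 0.32). Saline replicate 3 held 2052 CPM of miR-101a-3p; without it the log2 fold change of miR-101a-3p went from -1.26 to -0.51, that of miR-7b to -1.12 and that of miR-125b-2-3p to -0.58. No miRNA passed: 0 of 355 by the edgeR quasi-likelihood test (smallest adjusted p = 0.472), 0 by DESeq2 and 0 by limma voom, with 25 at an unadjusted p under 0.05. Chance gives 17.75 at that p, and the other splits of the libraries gave 3 to 77. Without saline replicate 1, 4 passed, namely miR-101a-3p, miR-143-3p, miR-154-5p (2.58) and miR-30a-3p, and without ketamine replicate 2, 1 passed.

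miR-143-3p, the abundant smooth muscle miRNA, made up 37.9% to 66.3% of miRNA counts per library and had a log2 fold change of -0.82 (SE 0.33, edgeR adjusted p = 0.533). Its partner miR-145-5p had -0.21 (SE 0.29). The miR-29 members, which repress collagen genes, had 0.25 (SE 0.28) for miR-29a-3p, 0.31 (SE 0.33) for miR-29b-3p and -0.01 (SE 0.27) for miR-29c-3p. On leaving out single libraries, miR-29a-3p ranged from 0.14 (without saline replicate 2) to 0.56 (without saline replicate 1), miR-29b-3p from 0.048 (without ketamine replicate 3) to 0.60 (without ketamine replicate 2) and miR-145-5p from -0.44 (without ketamine replicate 3) to -0.014 (without saline replicate 3). The epithelial miRNAs miR-200b-3p and miR-200c-3p had -0.19 (SE 0.36) and 0.19 (SE 0.29). Both arms of miR-21 were listed at 0 counts in all 6 libraries. Of 11 miRNA lists fixed beforehand, 0 passed with camera and 1 had an unadjusted p under 0.05; fry and camera with an estimated correlation also called 0. That list was the miR-17-92 cluster, with 5 of 7 arms negative, a median of -0.26 (-0.38 without ketamine replicate 1 to -0.083 without ketamine replicate 2), 0 arms passing when adjusted over the list alone, and a camera adjusted p of 0.307 (0.80 with an estimated correlation). The miR-29 family had a median of 0.26 (camera adjusted p = 0.478), and 0.11 without ketamine replicate 3.

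The circRNA comparison rested on the 264 junctions with enough reads to pass the filter. Of the 9473 listed, 6498 were seen in 1 library and 411 in all 6. Of the 6498, 4289 were seen in ketamine replicate 3 alone. On the higher side, a circRNA of the Myocd gene (chromosome 10, 51724607 to 51739115), which encodes the smooth muscle coactivator myocardin, had a log2 fold change of 0.84 (SE 0.42). One of Txndc11 had 1.19 (SE 0.56) and 2 intergenic ones on chromosomes 8 and 12 had 1.13 (SE 0.46) and 1.29 (SE 0.53). Without ketamine replicate 3 the Txndc11 circRNA had 0.42 and the intergenic one on chromosome 12 had 0.66. On the lower side, a circRNA of Ubn2 (chromosome 4, 66172555 to 66232564) had 24 to 35 reads per saline library and 15, 5 and 0 with ketamine, a log2 fold change of -2.63 (SE 1.11). Those of Rab6a, Larp1b and Dst had -0.98 (SE 0.44), -1.06 (SE 0.48) and -2.24 (SE 1.05), and an intergenic one on chromosome 3 had -2.14 (SE 0.87). On leaving out 1 library, the Ubn2 circRNA had -4.09 (without ketamine replicate 1) or -1.72 (without ketamine replicate 3), that of Dst -3.48 (without ketamine replicate 2), and without saline replicate 3 that of Rab6a had -0.63 and the one on chromosome 3 -1.40. None passed: 0 of 264 by the edgeR quasi-likelihood test, 0 by DESeq2 and 6, all lower, by limma voom, with 4 at an unadjusted edgeR p under 0.05, where chance gives 13.2 (smallest edgeR adjusted p = 0.932). limma voom gave the Ubn2 circRNA an adjusted p of 0.011, and the other 5 of its calls are not named. Scaled to the total reads of each library, an alternative chosen after seeing the data, the median log2 fold change of all tested circRNAs was 1.91, with 0 calls and 52 at an unadjusted p under 0.05; ketamine replicate 3 holds 9.24 times the mean junction reads of the other 5 libraries.

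Across 177 host genes, the mean log2 fold change of a gene's circRNAs and that of its mRNA had a Pearson r of 0.20 and a Spearman rho of 0.19. These describe genes, which are not independent replicates, and both values come from the same rats. Without saline replicate 2 the Pearson r was 0.08.

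**Figure D4:**
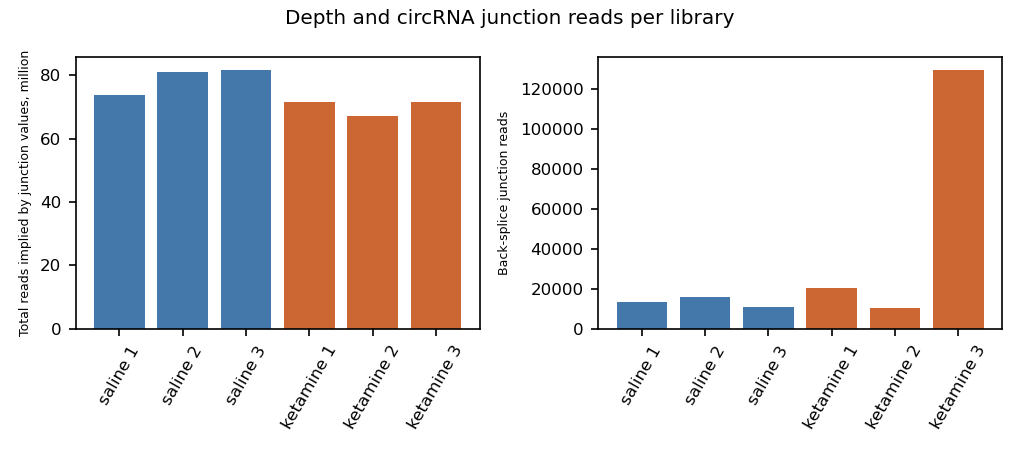
Total reads, as the deposited junction values imply them, and back-splice junction reads for each of the 6 libraries. Ketamine replicate 3 holds 129648 junction reads from 71505123 total reads, and the other libraries hold at most 20348 from 67173016 to 81756911.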

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

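Quantile normalization for the numbers of RNAs called (for lists and named RNAs it was fixed before), coding genes only, summed lncRNA loci, the mRNA table's scaling and scaling to total reads, and the estimated correlation without each library, were chosen after seeing the data; the other settings were fixed before the data were examined. No mRNA gene was called by edgeR under any filter, scaling or left-out library that was run, by voom, or by voom with library weights, while DESeq2 called 4. For lncRNAs, with 4 calls, DESeq2 gave 32, voom, voom with library weights and voom with quantile normalization gave 0 each, summed loci gave 1, and leaving out each library gave 1 to 10. All 4 calls were shared with DESeq2, RLE scaling, upper-quartile scaling, the stricter filter and the mRNA table's scaling, which gave 5 calls. Without saline replicate 2 the count was 1, without ketamine replicates 2 and 3 it was 10 each, and without saline replicates 1 and 3 it was 7 each. NONRATT003219.2 lost its call without ketamine replicate 1 and without ketamine replicate 2, MSTRG.18336.2 lost its call with no filter, which gave 3 calls, and without saline replicate 2 NONRATT026771.2 alone kept it. The log2 fold change of NONRATT003219.2 stayed between -5.22 and -4.83 on leaving out each library. For miRNAs, with 0 calls, no filter gave 3 and leaving out each library gave 0 to 4 (4 without saline replicate 1, 1 without ketamine replicate 2). The miRNA lists, with 0 calls, gave 0 to 1 on leaving out libraries (1 without ketamine replicate 2). For circRNAs, with 0 calls, no filter gave 4, voom 6 and voom with quantile normalization 1. Of the gene lists, 7 passed with the preset correlation, 0 with an estimated correlation, 0 with fry, 11 with camera on ranks, and 6 to 17 on leaving out each library (17 without ketamine replicate 1, 12 without saline replicate 2); with an estimated correlation, leaving out each library gave 0 lists, and 0 to 2 at an unadjusted p under 0.05. The correlation of circRNA and host fold changes ranged from 0.079 (without saline replicate 2) to 0.22 on leaving out libraries. Of 84 named RNAs with a test, the first 4 members of each called list included, 74 kept their direction under quantile normalization and without each library. With quantile normalization, the log2 fold change turned to -0.012 for Fn1, -0.15 for Acta2, -0.20 for Upk2, 0.086 for miR-29c-3p and 0.0064 for miR-145-5p. That setting makes the fold change of miR-143-3p 0 by construction, since it ranks first in every library, and was left out for it. On leaving out single libraries, the range was -0.040 to 0.36 for Fn1, -0.43 to 0.54 for Acta2, -0.069 to 0.56 for Timp1, -0.40 to 0.40 for Upk2, -1.04 to 1.30 for Ptgs2 and -4.61 to 0.45 for the immediate early gene Egr3 (0.45 without saline replicate 3), and it was -0.13 to 0.18 for miR-29c-3p, -0.83 to 0.13 for miR-200b-3p and -0.14 to 0.47 for miR-200c-3p. Of the 84, 48 moved by over 1.5 times or turned without at least 1 library, 29 of them without ketamine replicate 3. The list of immediate early and heat shock genes ranged from a median of -1.09 to 0.47. The median of all rows moved by more than 0.1 with the mRNA table's scaling for lncRNAs (-0.32), with upper-quartile scaling for miRNAs (0.19) and circRNAs (0.11), and for circRNAs with quantile normalization (0.12), no filter (2.10) and total reads (1.91). The causes of these changes were not tested.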

Other observations

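The list of Dlk1-Dio3 miRNAs and its tests, the tests of ketamine replicate 3, the 2 tests of overlapping lncRNA rows and the estimated correlation for the splits were chosen after seeing the results; the other tests of the lncRNA rows and the splits of the 6 counts were fixed before.

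The list of miRNAs of the imprinted Dlk1-Dio3 locus, a large cluster active in the embryo and in muscle and stroma, was made because the 5 named miRNAs on the higher side belong to it, so its tests describe a pattern and do not test it. Of 45 tested arms, 35 had positive and 10 negative values, with a median log2 fold change of 0.41; camera gave p = 2.0e-09 with the preset correlation and 0.039 with an estimated one, and 0 arms passed when adjusted over the list alone (1 with upper-quartile scaling and 1 without saline replicate 1). The median was 0.63 without saline replicate 1 and 0.31 without saline replicate 2. Without those 5 members, 30 of 40 arms were positive, with a median of 0.34, p = 1.7e-05 with the preset correlation, 0.066 with an estimated one and 0.077 with fry. The library medians were -0.10, -0.32 and -0.18 with saline and 0.33, 0.25 and 0.02 with ketamine. Of the genes beside the cluster, Dlk1 mRNA had a log2 fold change of 0.67 and Begain mRNA -0.05 (edgeR adjusted p = 0.925 and 0.992).

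Scaling shaped by the abundant miR-143-3p was tested as a cause. The list median was 0.37 with RLE, 0.58 with upper-quartile and 0.41 with quantile scaling, while the median of all miRNAs moved between -0.02 and 0.19, and a factor per library moves listed and other miRNAs alike. The distance between the list and the other miRNAs was therefore nearly fixed in advance under RLE and upper-quartile scaling, which cannot test it. Quantile scaling could change the distance and gave 0.38, against 0.41 in the main fit. Only that value speaks against scaling as the whole cause of the distance. A shift of all miRNAs would not be seen in it. The 10 splits of the libraries are too few for a test of chance: the real median was 0.412 and the highest other 0.409 in size.

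In the lncRNA table, 15 rows had at least 20 reads in each library of one group and at most 5 in each of the other. The 10 splits are too few for a test of chance, with 15 rows in the real split and 9 in the highest other, a difference of 6, and whether the groups were assembled or counted separately cannot be told from these data. For the 10 rows with an overlapping lncRNA row, the median size of the log2 ratio was 0.64 once the locus was summed, which a larger neighbour would also give, and the other rows made up a median of 0.24 of the row's change in CPM in the opposite direction (-0.39 to 3.10), so exchange of reads within a locus stays open. A locus chains overlapping rows, so its other rows can include some that do not overlap the row itself, as for MSTRG.18336.2 and MSTRG.42725.3. The median of 0.24 is thus a value for loci and not for overlapping rows alone. For 3 of the 10, MSTRG.9906.3, MSTRG.39706.2 and NONRATT014037.2, the summed CPM of the other rows changed the same way as the row. Singly, MSTRG.9906.2, MSTRG.39706.1 and NONRATT014035.2 fell (log2 ratios -0.23, -0.34 and -0.38), while MSTRG.9906.4 and NONRATT014036.2 rose (1.37 and 0.24). MSTRG.9906.2 had 580, 661 and 749 reads with saline and 587, 841 and 43 with ketamine, so its fall rests on ketamine replicate 3. The mRNA rows at 11 of the loci had a median log2 ratio of 0.020 in the direction of the lncRNA (-0.15 to 1.30), which speaks against the host gene's own level for these as a set, apart from NONRATT019429.2, whose overlapping gene had 1.30.

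Ketamine replicate 3 stood apart in ribosomal protein, oxidative phosphorylation and macrophage genes and in circRNA junction reads. Deeper sequencing did not account for it, since its implied total reads were 0.95 times the mean of the other 5 while its junction reads were 9.24 times theirs. Across 12587 coding genes, its log2 ratio to the others fell with gene length (Spearman rho -0.47, against 0.035 to 0.28 for the other libraries), consistent with more short transcripts in that library. Gene length here was inferred from counts and FPKM, with library totals inferred from the lncRNA rows, and is not an annotated length. Each library was set against the mean of the other 5, so ketamine replicate 3 is in the reference of every other library. The values of the other libraries are thus not independent of its own. In the log2 ratio of ketamine replicate 3 to the others, small structural RNAs such as 7SL and RNase MRP lay 1.68 above the macrophage genes. More leukocytes, by as much as the macrophage genes, would thus not alone give the structural RNA values. The median ratios of ribosomal protein, macrophage and oxidative phosphorylation genes were 2.21, 1.94 and 1.40. Structural RNAs are not among these genes, so the comparison cannot decide whether leukocytes account for them. A change in leukocytes was not excluded.

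For the other counts, the 10 splits are again too few for a test of chance. The real split and the highest other gave 0 and 0 mRNA genes, 4 and 5 lncRNAs, 0 and 10 miRNAs, 0 and 1 circRNAs, 7 and 20 gene lists, and 0 and 2 miRNA lists. Splits with at least as many calls as the real one, itself included, numbered 10 for mRNA genes, 3 for lncRNAs, 10 for miRNAs, 10 for circRNAs, 9 for gene lists and 10 for miRNA lists. The 5 to 20 gene lists of the other splits rest on the preset correlation, since with an estimated one all 10 splits gave 0 lists. The 10 miRNAs came from the split of saline replicate 1 and ketamine replicates 1 and 3 from the rest. What lies behind them was not tested.

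Both arms of miR-21, commonly abundant in tissue, were among 205 miRNA rows listed at 0 in all 6 libraries; how the table came to hold 0 was not tested.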
